A study of Mus musculus with 166 samples.

How the data were processed

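Open chromatin was profiled by Omni-ATAC-seq in 23 sorted cell types of young (2 months) and aged (22 to 24 months) C57/Bl6 mice, in 166 libraries, each from tissue pooled over 5 animals, per the labels. Per the submitters' processing notes, reads were trimmed with cutadapt 2.4, examined with FastQC 0.11.8 and aligned to GRCm38.p6 (mm10) with Bowtie2; Picard, SAMtools and bedtools were used on the alignments, and peaks were called with MACS2. Versions of the last 5 tools are not given in the sources used here. The authors deposited a table of read counts in 464754 peaks of 502 bases for the 166 libraries, and these counts were used as they stand. Even values make up 57.7% of its non-zero values, as counting both mates of a pair could give. How mates were counted was not tested, so counts may not be independent fragments. The authors also deposited a peak list per group with a score column that sums to the same total in each list; the scores were only checked, and the lists were used as intervals.

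Peaks were annotated with 21627 protein-coding genes of GRCm38.p6. The table of genes used here has no strand, so the planned distance to the start of transcription was replaced by the distance to either end of a gene. A gene-end peak has its centre within 1000 bases (2500 as an alternative) of either end of a gene (40984 peaks, 8.82%). A peak was linked to the gene that contains it (265126 peaks), and otherwise to the nearest gene within 50000 bases (100000 as an alternative), in total 391648 peaks and 19163 genes. The planned tests of sequence motifs need a genome sequence and were not run.

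Within each cell type, aged and young libraries were compared peak by peak with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr at its defaults), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Counts summed over the peaks linked to a gene were tested in the same way. Across cell types, log2 differences were tested with limma 3.58.1 with each cell type as 1 unit, over peaks or genes tested in at least 12 cell types. Gene lists were tested with camera, with a preset correlation of 0.01 and with an estimated one. The 13 lists held 11 to 20 genes each, with 200 of 204 memberships linked to peaks; Mx1, Mx2, H19 and Meg3 had no linked peak. The 26 marker lists had 156 of 158, without Ccl19 and Ccl21a. Shares were compared by exact two-sided sign tests over cell types. Recurrence was set against 100 shuffles of calls among peaks of like accessibility. Analyses used R 4.3.3, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

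Named peaks are, per cell type, the 2 opened and the 2 closed peaks with the lowest p among those past the threshold whose aged and young libraries do not overlap. Across cell types, the 12 higher and 12 lower genes with the lowest p are named, and of each list described up to 2 members that rose and 2 that fell. Cdkn2a, Cdkn1a, Fos, Jun and Tert are always named. Unnamed gene models and clustered receptor genes were passed over. A peak that this rule names in beta cells is not reported here. The windows of 10 peaks, the Ppm1h peak and Lncpint were looked at after the values were seen.

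Replicate numbers were checked for pairing by the correlation of same-numbered libraries' deviations from their group means, before calls were compared. Numbers were taken to pair the libraries where every same-number correlation was above 0.1. By this check of the data alone they did so in brain endothelium, muscle fibroblasts and the libraries labelled skin fibroblasts (lowest correlation 0.115). The 20 other types fell short of this limit, which does not show that pairing is absent there. Same-numbered libraries had a higher mean correlation than other pairs in 17 of 23 types. Liver progenitors (0.245 against -0.124) and keratinocytes (0.179 against -0.0589) were among them. The main fits do not use the numbers. In simulated data of 20000 peaks, changes of 0.5, 1 and 2 log2 units were recovered for 23.9%, 61.2% and 95.5% of changed peaks with the B cell libraries. The shares were 5.97%, 31.3% and 87.9% with neurons, 1.49%, 22.4% and 60.6% with satellite stem cells and 0%, 2.99% and 43.9% with haematopoietic stem cells. Unchanged simulated data gave 0 calls. The simulated libraries were drawn as independent, so this does not measure false calls among the real ones. In the test across cell types, changes of 0.25 and 0.5 were recovered for 65.5% and 91% of changed genes.

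Before the data were examined, these alternatives were fixed: DESeq2 1.42.0 with its own size factors, library size scaling, no low-count filter, the authors' peak list of the cell type as the tested peaks, the replicate number as a block, each replicate left out, the deposition set as a covariate (16 libraries were deposited later, per the labels) and other limits for the peak sets. An older edgeR fit, fits without libraries with markers of other cells, T cell types counted as 1, and fits without the chromosome 19 runs or without 2 aged libraries were added after seeing the data. Splits of the libraries of a cell type other than by age were tested on 10000 peaks.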

Results

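Accessible chromatin was measured in 23 cell types sorted from young and aged C57/Bl6 mice, to ask how accessibility differs with age in each type and which differences recur across types. The assay was Omni-ATAC-seq, in which a transposase cuts open DNA and the reads mark accessible sites. Young animals were 2 months old and aged animals 22 to 24 months old. Tissue from 5 animals was pooled for each replicate, per the labels, so the spread between libraries is the spread between pools. The 166 libraries (85 young, 81 aged) form 46 groups, 19 of them with 3 libraries, 26 with 4 and 1 with 5. Total counts ran from 6963107 in an aged naive CD4 T cell library to 72438788 in an aged liver progenitor library. The share of a library's counts inside its own cell type's peak list ran from 35.1% in an aged adipocyte library to 90.8%. Below, a peak that passed the test is called opened when it was higher in aged libraries and closed when it was lower. Differences are log2 values, aged minus young, with standard errors. Adjusted p-values of peaks and of genes within a cell type are from edgeR's quasi-likelihood test, those across cell types from limma, and those of gene lists from camera with a preset correlation unless stated.

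Own marker lists were compared over the sorted types. Linked counts of insulin and islet genes were highest in beta cells (7.09, mean log2 CPM over the list), those of neuronal genes in neurons (6.76) and those of the muscle stem cell genes Pax7 and Myf5 in satellite stem cells (7.18). The list for lymphatic endothelium, with Prox1 and Lyve1, stood at 4.0 in the lymph endothelial libraries and was higher in 8 other types, while the general endothelial list was the one that stood out there. Relative to other types, the list that stood out most was the erythroid one in haematopoietic stem cells, the mural cell one in lymph fibroblasts and the natural killer cell one in memory and virtual memory CD8 T cells. The 6 libraries labelled skin fibroblasts had the keratinocyte list, with Krt5, Krt14 and Trp63, at 7.44 ± 0.12 (SD, n = 6). This was near the 7.87 ± 0.12 (SD, n = 8) of keratinocytes and above the 4.30 ± 0.41 (SD, n = 30) of 30 libraries of other fibroblasts and fat progenitors. Their fibroblast list, with Pdgfra and Col1a1, was at 3.8 ± 0.15 (SD, n = 6), against 6.97 ± 0.13 (SD, n = 30) in those 30 libraries. They are therefore called libraries labelled skin fibroblasts throughout. In the labels, 2 of the 4 aged lymph fibroblast libraries carry conflicting descriptions, and counts of peaks without them are given with that cell type.

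**Figure D1:**
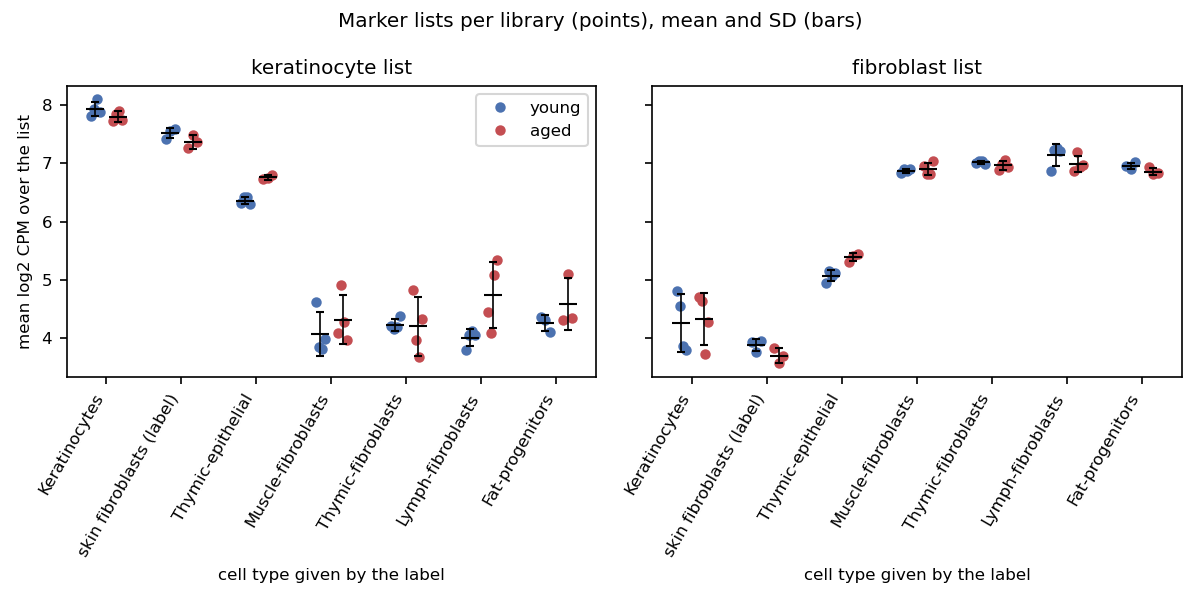
Mean log2 CPM of linked counts over the keratinocyte and the fibroblast marker list, 1 point per library. The 6 libraries labelled skin fibroblasts lie near keratinocytes on the keratinocyte list (7.44 against 7.87) and under the other fibroblast libraries on the fibroblast list (3.8 against 6.97).

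Thymic epithelium, adipocytes and T cells held most of the age differences. Thymic epithelial cells had 53569 opened and 47685 closed peaks, memory CD8 T cells 30694 and 30780, and memory CD4 T cells 30731 and 26327. Muscle fibroblasts (860 and 384), satellite stem cells (899 and 1028) and brain endothelial cells (1192 and 1216) had the fewest. Opened peaks outnumbered closed peaks in 14 cell types and closed peaks outnumbered opened ones in 9. The tally depends on the scaling and the peaks tested, with 10 and 13 types with library size scaling, 11 and 12 over the authors' peak lists and 16 and 7 with DESeq2. Opened shares ran from 11.4% of calls in neurons to 80.8% in the libraries labelled skin fibroblasts. These counts also follow the number of libraries and their spread. A change of 1 log2 unit in simulated data was recovered for 61.2% of peaks with the B cell libraries and for 2.99% with the haematopoietic stem cell libraries. Leaving out a single library moved the count by over 1.5 times for 63 of the 166 libraries.

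**Figure D2:**
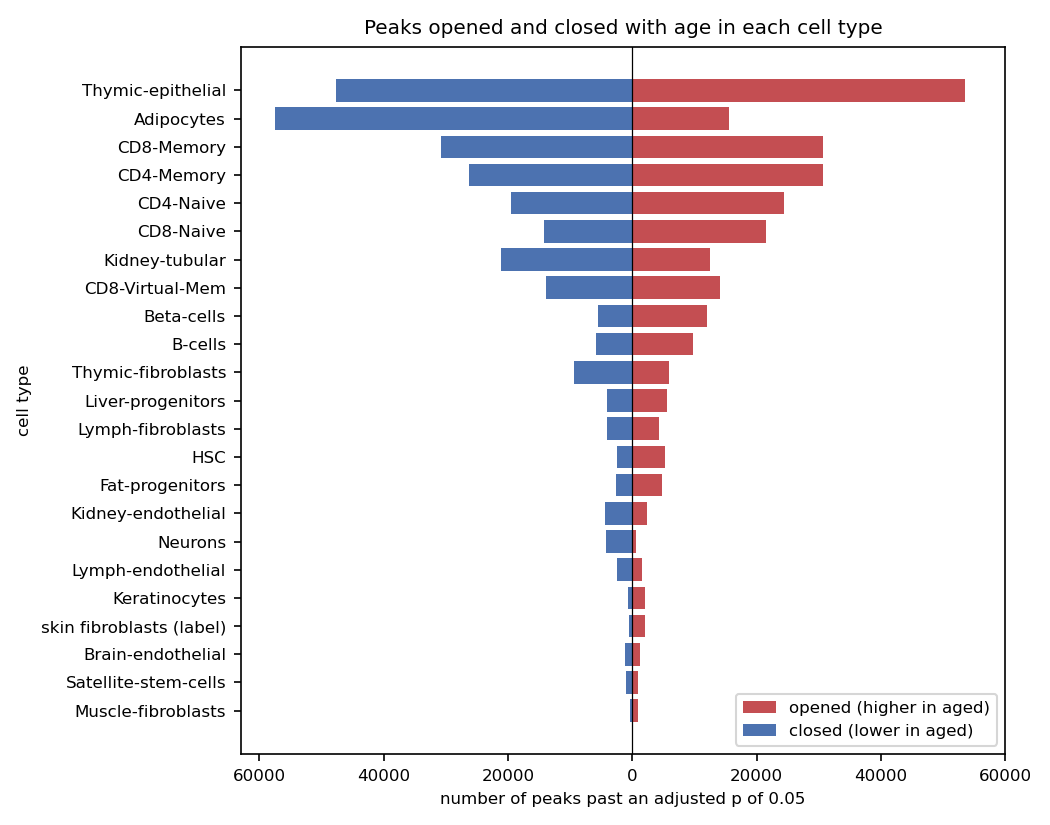
Number of peaks opened (higher in aged) and closed (lower in aged) in each of the 23 cell types at an edgeR adjusted p of 0.05. Thymic epithelium has 53569 opened and 47685 closed peaks and muscle fibroblasts 860 and 384.

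Across cell types, taking each type as 1 unit, 463 of 231609 peaks opened while 281 closed. Among 18412 genes, 94 rose and 31 fell in counts summed over linked peaks. Sp110, an interferon-induced nuclear body protein, rose by 0.47 ± 0.06 (adjusted p = 3.8e-04, higher in 21 of 23 types). The class Ib major histocompatibility genes H2-Q6 (0.54 ± 0.09), H2-Q7 (0.46 ± 0.07) and H2-Q1 (0.33 ± 0.05) rose as well, H2-Q6 by up to 1.73 in brain endothelium. Gvin1, an interferon-inducible GTPase, rose by 0.71 ± 0.13 (higher in 20 of 23 types) and Fetub by 0.57 ± 0.10. Plekhb2 rose by 0.20 ± 0.03 (higher in 23 of 23) and the histone variant gene H2al1k by 1.21 ± 0.19. Sp110, Gvin1, H2al1k and the H2-Q genes belong to clusters of near-identical copies, so their counts are uncertain. Genes that fell included Nmnat1, which makes nuclear NAD (-0.42 ± 0.08, lower in 19 of 23), Pabpc4l (-0.43 ± 0.09), the Wnt inhibitor Apcdd1 (-0.33 ± 0.07), Acbd7 (-0.25 ± 0.06), Colec11 (-0.24 ± 0.05), Wnt2b (-0.24 ± 0.05), the cohesion factor Dscc1 (-0.21 ± 0.04), Ppp1r14b (-0.19 ± 0.04), Fam83d (-0.19 ± 0.03), Ttc28 (-0.18 ± 0.04), Casp6 (-0.14 ± 0.03) and catalase, Cat (-0.10 ± 0.02), each with an adjusted p between 0.0111 and 0.0352. Related types are not independent, and with 8 classes of cell types as units 10 peaks opened and 2 closed, and 5 genes rose and 0 fell. Without adipocytes 1232 peaks opened and 941 closed, and without naive CD8 T cells 186 and 51.

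The 4 genes with the lowest p across cell types lay on chromosome 19. Their differences may reflect the cohort of mice in place of age, as weighed below. Btaf1, a regulator of the TATA-binding protein, rose by 0.79 ± 0.03 in linked counts (adjusted p = 5.0e-17) and passed the test in 23 of 23 types. The mitotic kinesin gene Kif11 rose by 0.68 ± 0.03 and passed in 20, Fgfbp3 by 0.70 ± 0.04 and passed in 21, and Ide, the insulin-degrading enzyme gene, by 1.07 ± 0.09 and passed in 18. All lie in or beside 3 runs of peaks (19:36916795-36973977, 19:37238505-37266189 and 19:37298223-37420048, mm10) that hold 80 peaks. Peaks outside the cell type's own peak list rose there by 0.87 over their flanks (SD 0.24 over 23 cell types) and listed peaks by 0.81 (SD 0.17). Of the 81 aged libraries, 80 lay above every young library of their cell type in the ratio of these runs to their flanks. Without the genes of these runs 88 genes rose and 31 fell across cell types, and without their peaks 371 peaks opened and 228 closed. Of the peaks first called opened, 32 lay in the runs and 431 outside, and of those called closed 0 lay in them. The numbers without these peaks thus fell by more than the peaks of the runs.

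One peak inside Ppm1h, a protein phosphatase gene, was near absent from aged libraries of every type. At 10:122806718-122807219 the 85 young libraries held 11 to 241 counts each, and 79 of the 81 aged libraries held 0 to 7, with 0 in 49 of them. It was the only 1 of 464754 peaks that differed by over 1.5 log2 units in the same direction in all 23 cell types. The exceptions were B cell aged library 4 (97 counts) and virtual memory CD8 aged library 4 (173 counts), whose chromosome 19 ratios lay 0.19 and 0.02 above the young means. The first lay above every young B cell library and far under the other aged ones (0.94 to 0.96), and the second lay within the young range. Without these 2 libraries, a choice made after seeing the data, 376 peaks opened and 220 closed across cell types.

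**Figure D3:**
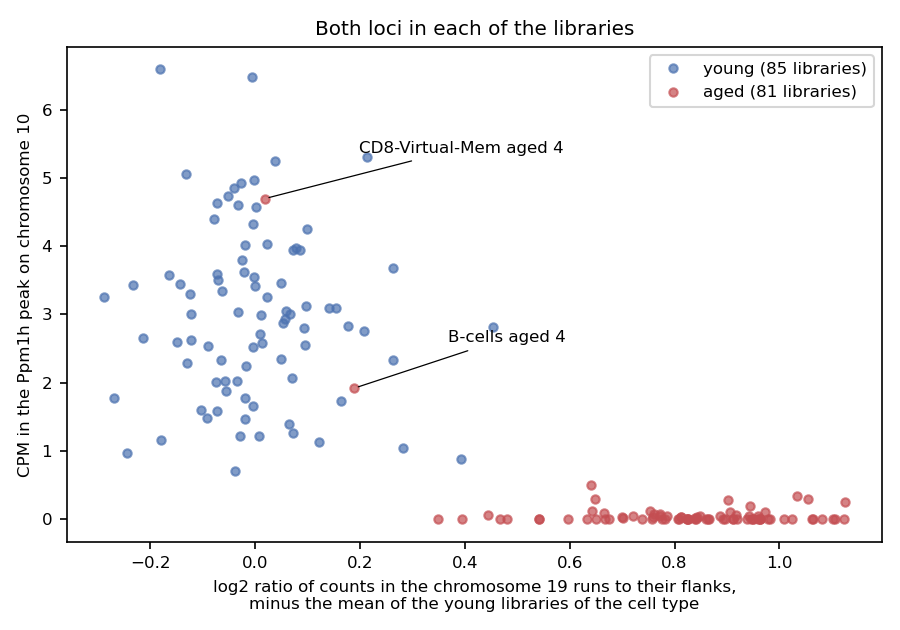
CPM in the Ppm1h peak against the log2 ratio of counts in the chromosome 19 runs to their flanks, minus the young mean of the cell type, 1 point for each of 85 young and 81 aged libraries. B cell aged library 4 (0.19) and virtual memory CD8 aged library 4 (0.02) lie near the young libraries on both axes.

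Antigen presentation genes rose together across cell types. Of 13 members, 5 rose over all genes and 11 when adjusted over the list alone, with all 13 higher on average, among them the class I transactivator Nlrc5 (0.18 ± 0.04) and the immunoproteasome subunit Psmb8 (0.22 ± 0.05). The list rose relative to other genes (camera adjusted p = 1.1e-15, and adjusted p = 1.1e-05 with an estimated correlation). All list tests in this paragraph take each cell type as 1 unit, although related types are not independent. They were not repeated with the 8 classes of cell types as units, so their p-values may be too low. In the interferon response list 2 of 18 members rose over all genes and 4 adjusted over the list alone, including Isg15 (0.17 ± 0.04) and Oas1a (0.42 ± 0.10), and the list rose (adjusted p = 2.2e-06, and adjusted p = 0.0208 with an estimated correlation). The interferon call was lost over the authors' peak lists (7 genes, adjusted p = 0.203, and 0.315 with an estimated correlation) and, with an estimated correlation, with the replicate block (adjusted p = 0.0579). The other 7 calls over cell types did not pass with an estimated correlation in the same fit. T cell effector and exhaustion genes rose (adjusted p = 4.1e-08, and adjusted p = 0.119 with an estimated correlation), with Prdm1 (0.22 ± 0.05) past the threshold over all genes and 6 of 17, Eomes (0.30 ± 0.10) among them, adjusted over the list alone. Imprinted and juvenile growth genes fell (adjusted p = 1.7e-05, and with an estimated correlation adjusted p = 0.053, 0.0466 with DESeq2 and 0.0412 with no low-count filter), with 1 of 15 past the threshold over all genes, the RNA-binding protein gene Igf2bp3 (-0.29 ± 0.07), and 7 adjusted over the list alone, Mycn (-0.42 ± 0.13) among them. Immediate-early genes (adjusted p = 3.9e-04) and AP-1 genes (adjusted p = 0.0017) rose, each with an adjusted p = 0.278 with an estimated correlation. In the AP-1 list Fosl1 (0.18 ± 0.03) rose over all genes, and Batf (0.20 ± 0.05) and Batf3 (-0.10 ± 0.04, but 0.013 over gene-end peaks alone, limma adjusted p = 0.974) changed adjusted over the list alone, as did Ier3 (0.26 ± 0.08) in the immediate-early list. NF-kB and cytokine genes rose (adjusted p = 8.8e-04, and adjusted p = 0.119 with an estimated correlation) with 0 of 18 members past either threshold, and the call was lost over the authors' lists (adjusted p = 0.186). Extracellular matrix genes (adjusted p = 0.0012) and naive T cell genes (adjusted p = 0.0090) fell, both with an adjusted p = 0.304 with an estimated correlation, and all 15 and all 11 members were lower on average with 0 past either threshold. The matrix call was lost over the authors' lists (5 genes, median 0.013, adjusted p = 0.807). Cell cycle (adjusted p = 0.0631), senescence (adjusted p = 0.0810), circadian clock (adjusted p = 0.557) and mitochondrial genes (adjusted p = 0.883) did not pass. Over gene-end peaks alone cell cycle genes fell (adjusted p = 0.0039, and adjusted p = 0.227 with an estimated correlation).

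**Figure D4:**
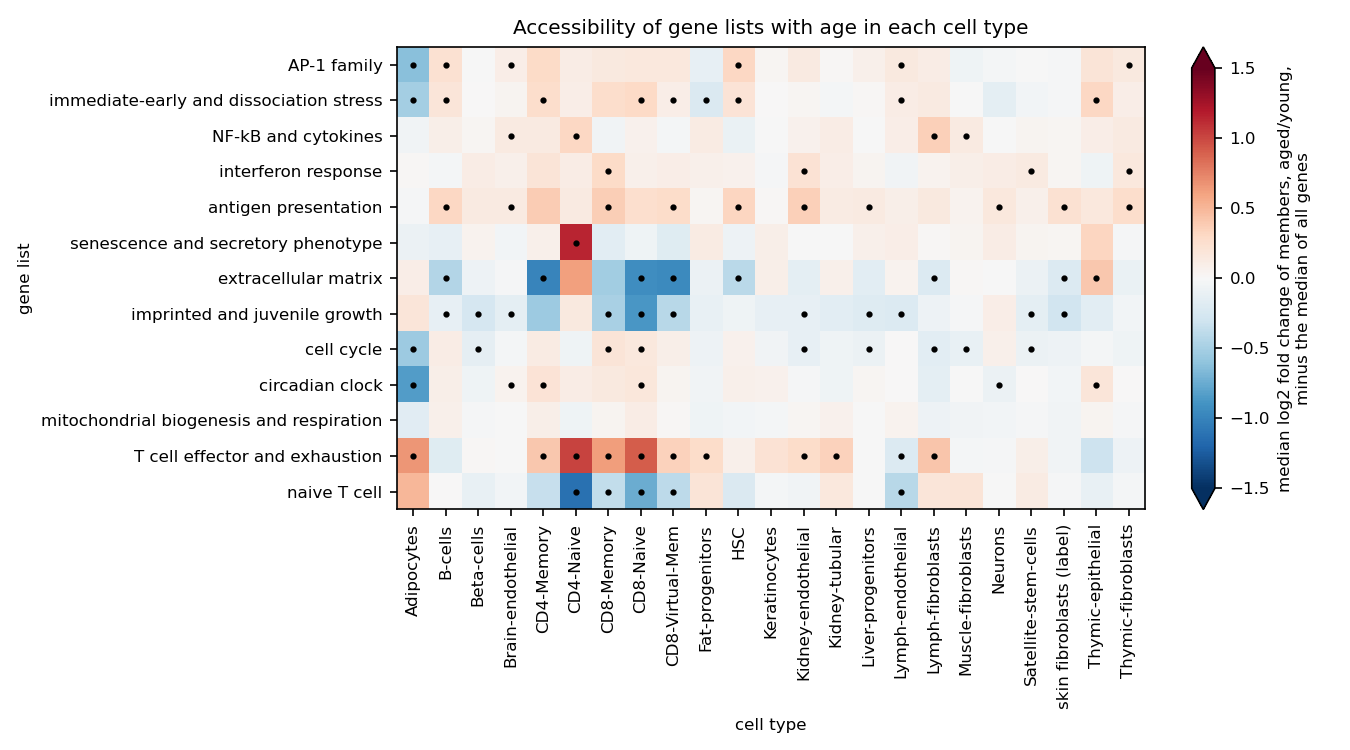
Median log2 difference, aged minus young, of each of the 13 gene lists in each of the 23 cell types, with marks for the list tests that passed at the preset correlation. Antigen presentation is called up in 10 cell types and down in 0, and imprinted and juvenile growth down in 11 and up in 0.

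Cdkn2a, which encodes the cell cycle inhibitor p16, had linked counts higher by 0.53 ± 0.13 across cell types (adjusted p = 0.063 over all genes, 0.0068 adjusted over the list alone, higher in 20 of 23). It rose in 8 types and fell in 0, by 2.57 ± 0.25 in naive CD4 and 2.12 ± 0.21 in naive CD8 T cells. Cdkn1a averaged 0.06 ± 0.04 and rose in 2 types and fell in 1. Jun averaged 0.09 ± 0.06, rising in 4 types and falling in 1, and Fos 0.02 ± 0.04, rising in 2 and falling in 1, with adipocytes the type in which both fell (-0.81 ± 0.10 and -0.55 ± 0.09). Tert, the telomerase gene, averaged -0.14 ± 0.07, fell in 5 types and rose in 1. The adjusted p-values of these 4 genes over cell types were 0.521, 0.469, 0.871 and 0.418.

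Within single cell types 84 of 299 list tests passed at the preset correlation (48 up, 36 down) and 0 with an estimated correlation, where 20 had an unadjusted p under 0.05. The lowest adjusted p with an estimated correlation was 0.282, and the values given below for each list are of this kind. Of the 84 calls 81 were also made with library size scaling and 83 with size factors of the DESeq2 kind, with 0 in the opposite direction. The test of DESeq2 itself was not run on these lists. Only the scaling differs in these settings, and it moves the genes of a library together, so they hardly test the calls. Over the authors' own peak lists, which change the counts, 47 were made, again with 0 in the opposite direction. Of 598 tests of marker lists 18 passed at the preset correlation and 0 with an estimated correlation. Whether a different share of other cells in the sorts moved these markers was not tested. Nor was it tested in any cell type whether the share of counts in the own peak list moved the lists.

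Naive CD4 T cells gained accessibility at effector genes and lost it at genes of the naive state. T cell effector and exhaustion genes rose in 12 of 17 members (12 adjusted over the list alone), with Gzmk, a granzyme of memory cells, up by 4.76 ± 0.41 and Tox2 by 1.02 ± 0.09, and naive T cell genes fell in 10 of 11 (10), with Lef1 at -1.16 ± 0.17 and Il7r at -1.14 ± 0.16. The list tests had adjusted p = 4.5e-06 and 5.5e-06, and adjusted p = 0.537 with an estimated correlation for both. Cdkn2b rose by 2.36 ± 0.22 and Ccl5 by 3.82 ± 0.27. Among 24443 opened and 19588 closed peaks (15148 and 15782 over the authors' own peak list) were one in Osbpl3 (6:50393969-50394470, 35.1 ± 5.80 CPM in aged, n = 3, and 1.01 ± 0.285 in young, n = 4; 5.13 ± 0.23) and one in Neb (2:52319080-52319581, 4.0 ± 0.19). Closed peaks lay in Ppm1h (10:122807245-122807746) and Ntrk2 (13:59025558-59026059, -3.01 ± 0.25). Of the peaks most specific to this type 57.6% closed and 6.51% opened.

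In memory CD4 T cells effector genes rose in 11 of 17 members (12 adjusted over the list alone; adjusted p = 1.4e-04, and adjusted p = 0.537 with an estimated correlation), with Gzmk at 1.45 ± 0.10 and the T helper 1 factor Tbx21 at 0.54 ± 0.10. Immediate-early genes rose in 8 of 17 (8), with Socs3 at 0.58 ± 0.09 and Klf6 at 0.60 ± 0.12 (adjusted p = 0.645 with an estimated correlation), and extracellular matrix genes fell in 10 of 15 (13), with Ccn2 at -0.78 ± 0.18 (adjusted p = 0.651 with an estimated correlation). The share of counts in the own peak list was 87.2% ± 1.19 in aged and 77.9% ± 7.29 in young libraries (SD, n = 4 each). Whether this lower share in young libraries moved the lists was not tested. Opened peaks lay near Tmem45a2 (16:57030418-57030919, 34.7 ± 2.59 CPM in aged and 5.47 ± 0.07 in young, n = 4 each; 2.67 ± 0.15) and in Ly6g6c (17:35068482-35068983, 3.63 ± 0.23). Those that closed lay in Ppm1h (10:122807245-122807746) and Arpp21 (9:112174719-112175220, -2.80 ± 0.22). The split of 30731 opened and 26327 closed peaks became 14467 and 43470 with library size scaling, and 14619 and 20207 over the authors' own peak list.

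In naive CD8 T cells effector genes rose in 16 of 17 members (16 adjusted over the list alone), with Gzmk at 4.95 ± 0.45 and Tbx21 at 1.96 ± 0.17, and naive genes fell in 8 of 11 (10), with Il7r at -1.03 ± 0.19 and Tcf7 at -0.67 ± 0.17 (adjusted p = 0.537 and 0.606 with an estimated correlation). The endothelial marker list fell (median -0.82, 4 of 8 members, adjusted p = 0.876 with an estimated correlation). The clock genes Bhlhe40 (2.03 ± 0.18) and Per3 (1.85 ± 0.18) and the stress genes Nr4a2 (1.18 ± 0.13) and Ier3 (1.28 ± 0.15) rose. An opened peak in Ankrd44 (1:54660633-54661134) went from 3.35 ± 0.61 to 64.1 ± 15.8 CPM (n = 4 each; 4.30 ± 0.21), and another lay near Fam180a (6:35373986-35374487, 7.45 ± 0.40). A peak in Snd1 (6:28929122-28929623) closed by -6.26 ± 0.56, as did the first Ppm1h peak. Of 21494 opened and 14157 closed peaks, 16156 and 21919 were found with library size scaling. Without aged library 3 the calls numbered 21966, and without young library 3 23724.

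Memory CD8 T cells gained accessibility at effector and interferon genes. Effector genes rose in 14 of 17 members (16 adjusted over the list alone), with Gzmk at 2.56 ± 0.14 and Tbx21 at 0.84 ± 0.07, and interferon genes in 11 of 18 (11), with Irf7 at 0.58 ± 0.06 and Ifit3 at 0.96 ± 0.11 (adjusted p = 0.537 and 0.479 with an estimated correlation). Antigen presentation genes rose in 7 of 13 and fell in 1, Ciita (-0.40 ± 0.13), and naive genes fell in 6 of 11, with Foxp1 at -0.86 ± 0.09 (adjusted p = 0.583 and 0.71 with an estimated correlation). Beside these, the endothelial marker list fell (median -0.70) and the CD8 list rose (median 0.67; adjusted p = 0.876 with an estimated correlation for both). Peaks in Cit (5:115854347-115854848, 2.74 ± 0.44 to 33.8 ± 2.37 CPM, n = 4 each; 3.61 ± 0.14) and Cdhr5 (7:141270572-141271073, 3.19 ± 0.14) opened. Peaks in Tnni1 (1:135807532-135808033, -2.96 ± 0.15) and near Slc38a6 (12:73383870-73384371, -4.80 ± 0.32) closed. The split of 30694 and 30780 became 18389 and 48098 with library size scaling.

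Virtual memory CD8 T cells had 14088 opened and 13896 closed peaks, 11059 and 16210 with library size scaling and 9281 and 10829 over the authors' own peak list. A peak in Runx3 (4:135169014-135169515), a gene of the CD8 lineage, rose from 4.33 ± 1.03 to 43.0 ± 3.72 CPM (n = 4 each; 3.24 ± 0.15), and one near Bhlhe40 (6:108672064-108672565) by 4.18 ± 0.21. Peaks in Mical3 (6:120934131-120934632, -2.49 ± 0.12) and Dgkg (16:22526316-22526817, -3.98 ± 0.20) closed. Effector genes rose in 8 of 17 members and fell in 1, with Tbx21 at 1.01 ± 0.09 and Lag3 at -0.34 ± 0.10, and naive genes fell in 7 of 11, with Lef1 at -0.76 ± 0.06 and Ccr7 at -0.82 ± 0.07 (adjusted p = 0.537 with an estimated correlation for both). The adipocyte marker list fell (median -0.65, 3 of 7 members, adjusted p = 0.876 with an estimated correlation). Mycn fell by 2.34 ± 0.26 and H2-K1 rose by 0.43 ± 0.08. Without young library 1 there were 17429 calls.

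In B cells AP-1 genes rose in 8 of 14 members (9 adjusted over the list alone), with Fosb at 0.84 ± 0.08 and Junb at 0.39 ± 0.05, and immediate-early genes in 9 of 17 (13), with Egr3 at 0.36 ± 0.05 and Zfp36 at 0.37 ± 0.05 (adjusted p = 0.324 and 0.282 with an estimated correlation). Antigen presentation genes rose in 7 of 13 (8), with H2-Aa at 0.58 ± 0.06 and H2-Ab1 at 0.44 ± 0.06, and extracellular matrix genes fell in 10 of 15 (11), with Col6a1 at -0.64 ± 0.10 (adjusted p = 0.537 with an estimated correlation for both). The fibroblast marker list fell as well (median -0.35, adjusted p = 0.876 with an estimated correlation). The share of counts in the own peak list was 87.1% ± 0.529 in aged and 85.3% ± 0.283 in young libraries (SD, n = 4 each). Peaks in Pdp2 (8:104596074-104596575, 1.98 ± 0.26 to 8.35 ± 0.62 CPM, n = 4 each; 2.10 ± 0.15) and Bop1 (15:76461488-76461989, 1.77 ± 0.13) opened. Peaks in Plxna2 (1:194619590-194620091, -1.64 ± 0.11) and the imprinted Gnas locus (2:174295253-174295754, -2.88 ± 0.20) closed. The split of 9788 opened and 5774 closed became 5376 and 8754 with library size scaling and 5384 and 6971 over the authors' own peak list, and there were 7697 calls without young library 1 and 7994 without young library 3.

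In haematopoietic stem cells the AP-1 gene Fosb (0.50 ± 0.09), the stress genes Nr4a2 (0.63 ± 0.10) and Klf6 (0.64 ± 0.12) and the class II chaperone Cd74 (0.47 ± 0.08) rose. AP-1 genes rose in 1 of 14 members (7 adjusted over the list alone), antigen presentation genes in 1 of 13 (7), and extracellular matrix genes fell in 0 of 15 (11), with adjusted p = 0.537, 0.537 and 0.562 with an estimated correlation. The B cell marker list fell (median -0.45, adjusted p = 0.876 with an estimated correlation). The share of counts in the own peak list was 83.7% ± 2.44 in aged (SD, n = 4) and 70.3% ± 14.3 in young libraries (SD, n = 3). Whether this lower share in young libraries moved the lists was not tested. Of 5170 opened and 2440 closed peaks, those in Mfsd1 (3:67601442-67601943, 0.57 ± 0.27 to 8.55 ± 1.02 CPM, n = 3 young and 4 aged; 4.06 ± 0.46) and Mapk10 (5:103193641-103194142, 3.58 ± 0.42) opened, and those in Tshz1 (18:84063747-84064248, -2.70 ± 0.32) and Farp1 (14:121268793-121269294, -2.46 ± 0.32) closed. These counts rest on single libraries, with 3 calls without young library 3, 153357 without young 2, 4055 without young 1, and 12732, 2923, 1881 and 2333 without aged 1 to 4. The split was 7420 and 425 with DESeq2, 6183 and 5089 with library size scaling and 5606 and 6601 over the authors' own peak list.

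In the thymic epithelial libraries T cell markers were low and fell with age (Cd8a 16.3 ± 0.578 CPM, SD, n = 4, to 3.61 ± 1.14, SD, n = 3). A lower share of thymocytes in the aged sorts was not told apart from a change in the epithelium. In the T cell marker list 6 of 7 members fell, with Lat at -1.72 ± 0.16, and Cd8a (-2.07 ± 0.15) and Cd8b1 (-2.08 ± 0.15) fell in the CD8 list, while 6 of 7 keratinocyte markers rose, with Perp at 0.80 ± 0.08 and Krt14 at 0.56 ± 0.06 (adjusted p = 0.876 with an estimated correlation for each list). Immediate-early genes rose in 14 of 17 members (14 adjusted over the list alone), with Gadd45b at 0.76 ± 0.06, clock genes in 8 of 16 (9), with Cry1 at 0.61 ± 0.05, and matrix genes in 9 of 15 (10), with Fbn1 at 0.76 ± 0.08 and Fn1 falling by 1.0 ± 0.09 (adjusted p = 0.537, 0.645 and 0.537 with an estimated correlation). Peaks in Ptpn5 (7:47108841-47109342, 0.542 ± 0.135 in young, n = 4, to 14.9 ± 1.06 CPM in aged, n = 3; 4.75 ± 0.22) and Gatd3a (10:78162615-78163116, 3.83 ± 0.18) opened. Peaks near Spertl (14:95877085-95877586, -4.0 ± 0.28) and in Chd6 (2:160948111-160948612, -2.88 ± 0.22) closed. The split of 53569 and 47685 became 40988 and 65507 with library size scaling.

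Thymic fibroblasts had 5861 opened and 9454 closed peaks. Interferon genes rose in 3 of 18 members (4 adjusted over the list alone), with Oas1a at 0.74 ± 0.14, and antigen presentation genes in 3 of 13 (8), with H2-Ab1 at 0.53 ± 0.08 (adjusted p = 0.537 with an estimated correlation for both). Peaks in Ldah (12:8295479-8295980, 2.31 ± 0.19) and near the natural killer receptor gene Klra8 (6:130092490-130092991, 4.77 ± 0.49) opened, and one near Padi2 (4:140883741-140884242, -2.81 ± 0.22) and the first Ppm1h peak closed. The split was 5434 and 5251 with DESeq2, and there were 5813 calls without aged library 2, 7695 without young 1 and 6327 without young 2.

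In kidney endothelium antigen presentation genes rose in 5 of 13 members (10 adjusted over the list alone), with Cd74 at 2.08 ± 0.13 and H2-Aa at 0.87 ± 0.10, and interferon genes in 2 of 18 (4), with Stat2 at 0.99 ± 0.16 (adjusted p = 0.537 with an estimated correlation for both). A peak 96 bases from Cd74 (18:60803503-60804004) rose from 2.01 ± 0.46 (SD, n = 4) to 15.1 ± 3.96 CPM (SD, n = 3; 2.96 ± 0.23), and one in Cntnap5a (1:116276539-116277040) by 4.64 ± 0.46. A peak 62 bases from Sox11 (12:27342530-27343031), a developmental transcription factor gene, closed (-3.97 ± 0.30), as it did in 8 of the 18 types in which it was tested, and one near Tmem132e (11:82339927-82340428) by -2.34 ± 0.20. The split of 2380 and 4418 was 3188 and 3434 with library size scaling and 3871 and 4525 over the authors' own peak list, with 3222 calls without aged library 1 and 3246 without aged 4.

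Brain endothelium had 1192 opened and 1216 closed peaks. A peak 45 bases from H2-Q6 (17:35424555-35425056) rose from 7.15 ± 1.99 to 34.9 ± 6.07 CPM (SD, n = 4 each; 2.29 ± 0.18) and one 65 bases from Prkcz, a protein kinase C gene (4:155361243-155361744), by 2.48 ± 0.20. A peak beside Auts2 (5:132542985-132543486) closed by -2.24 ± 0.20, and the first Ppm1h peak held 2.56 ± 1.08 CPM in young and 0 counts in all 4 aged libraries. Antigen presentation genes rose in 2 of 13 members (2 adjusted over the list alone), Nlrc5 (0.38 ± 0.07) and H2-Ab1 (0.46 ± 0.11), and the imprinted genes fell in 3 of 15 (4), with Mest at -0.70 ± 0.12 (adjusted p = 0.537 with an estimated correlation for both). The split was 951 and 1610 with DESeq2 and 1815 and 2994 with library size scaling, with 890 calls without aged library 2, 755 without aged 4 and 757 without young 3.

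Lymph endothelium lost accessibility at Sox11 (-3.32 ± 0.30 at the same peak). The B cell marker list fell (median -0.93, 0 members past the threshold over all genes, marker list adjusted p = 6.0e-07, and adjusted p = 0.876 with an estimated correlation), and the naive T cell list fell with it (median -0.41), with Ccr7 at -0.66 ± 0.09 (adjusted p = 0.537 with an estimated correlation). Among the imprinted and growth genes 2 of 15 fell (4 adjusted over the list alone), Sox11 (-2.47 ± 0.22) and Peg3 (-1.22 ± 0.13), with adjusted p = 0.537 with an estimated correlation. The Prkcz peak opened by 1.84 ± 0.17 and one in Phactr3 (2:178327326-178327827) by 2.64 ± 0.27. The split of 1562 and 2505 was 1126 and 3369 with library size scaling and 1028 and 985 over the authors' own peak list, and the calls numbered 265 without aged library 2, 2614 without aged 3, 1558 without young 2 and 139 without young 3.

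Lymph fibroblasts gained accessibility at 3 of 18 NF-kB genes (8 adjusted over the list alone), among them Nfkb1 (0.71 ± 0.10) and the chemokine Cxcl1 (0.54 ± 0.10). The list did not pass with an estimated correlation (camera adjusted p = 0.479). These gene and list values include aged libraries 1 and 2. They were not refitted without them or with the deposition set as a covariate. A peak in Ptgs2, the inducible cyclooxygenase gene (1:150105227-150105728), opened by 2.65 ± 0.30 and one near Nsd1 (13:55189419-55189920) by 2.23 ± 0.21. Histone gene peaks on chromosome 13 closed, at H3c11 (13:21783195-21783696, -2.93 ± 0.28) and H2ac8 (13:23571030-23571531, -2.03 ± 0.20); these clusters hold near-identical genes and are uncertain. The 4348 opened and 4053 closed peaks became 14736 and 2641 without aged libraries 1 and 2, whose labels conflict, and 525 and 69 with the deposition set as a covariate. Aged libraries 1 and 2 are also the only ones of this type in the earlier deposition set, so both alternatives concern the same libraries. Single libraries moved the calls to 3245 (without aged 1), 3611 (aged 2), 2446 (young 2) and 3734 (young 4).

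Muscle fibroblasts closed the first Ppm1h peak and the H2ac8 peak (-2.48 ± 0.24) and opened peaks near Ang2 (14:51199393-51199894, 1.58 ± 0.20) and Myh9 (15:77848539-77849040, 1.89 ± 0.24). The endothelial marker list fell with age (median -0.39; 0 of 8 members over all genes, 4 adjusted over the list alone, list adjusted p = 0.876 with an estimated correlation). The 860 opened and 384 closed peaks became 2936 and 1957 with the replicate block, whose numbers pair here, and 1544 and 574 without aged library 2 and young library 1, which held more markers of other cells. Without 1 library the calls numbered 303 (aged 1), 85 (aged 4), 1924 (young 1), 214 (young 2), 112 (young 3) and 248 (young 4).

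Fat progenitors closed peaks beside the histone genes H1f5 (13:21779238-21779739, 16.2 ± 1.26 to 1.84 ± 0.885 CPM, n = 3 each; -3.00 ± 0.25) and H2ac15 (13:21753710-21754211, -2.61 ± 0.27), and opened peaks near Pramel29 (4:144225734-144226235, 4.37 ± 0.38) and Zfp996 (12:18387192-18387693, 3.11 ± 0.30). Of 17 immediate-early genes 1 fell (4 adjusted over the list alone), the heat shock gene Dnajb1 (-0.53 ± 0.10; list adjusted p = 0.696 with an estimated correlation). The split of 4817 opened and 2622 closed turned to 51 and 116 with no low-count filter. The calls numbered 2778 without aged library 4, 2378 without young 1, 2062 without young 2 and 2868 without young 4.

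Satellite stem cells closed the Sox11 peak, from 16.8 ± 2.05 (SD, n = 3) to 2.24 ± 0.62 CPM (SD, n = 4; -2.83 ± 0.23), and the H2ac8 peak (-2.81 ± 0.25), and opened peaks in Grin2a (16:9833907-9834408, 2.55 ± 0.25) and near Cyp2a12 (7:27059251-27059752, 2.78 ± 0.29). Sox11 also fell in linked counts (-2.12 ± 0.11), 1 of 15 imprinted and growth genes to do so (3 adjusted over the list alone; list adjusted p = 0.537 with an estimated correlation). The 899 opened and 1028 closed peaks became 2860 and 3297 without aged library 2 and young library 1, which held more markers of other cells. With the deposition set as a covariate they became 132 and 46. Of the aged libraries only 4 was deposited in the same set as the young ones. Deposition and age are thus hardly told apart here, and this fit is no test of a batch. Single libraries moved the calls to 665 (without aged 3), 641 (aged 4), 4211 (young 1), 461 (young 2) and 285 (young 3).

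Keratinocytes closed a peak in the imprinted gene Peg3 (7:6728466-6728967), from 22.1 ± 7.73 to 0.88 ± 0.43 CPM (SD, n = 4 each; -4.71 ± 0.37), and one in Negr1 (3:156933836-156934337, -3.45 ± 0.33). They opened peaks in Pid1 (1:84097373-84097874, 3.75 ± 0.29) and Zfp804b (5:7176458-7176959, 3.13 ± 0.32). The libraries labelled skin fibroblasts closed the same Peg3 peak (-2.84 ± 0.19) and one in Sema6d (2:124509376-124509877, -3.8 ± 0.28), and opened peaks in Adcy2 (13:68838053-68838554, 3.04 ± 0.26) and Pcolce2 (9:95694922-95695423, 3.37 ± 0.30). In these libraries imprinted and growth genes fell in 3 of 15 members (7 adjusted over the list alone), with Peg3 at -2.22 ± 0.11 and Dlk1 at -0.83 ± 0.10, and antigen presentation genes rose in 1 of 13 (7), H2-Eb1 at 0.40 ± 0.08 (adjusted p = 0.537 and 0.346 with an estimated correlation), and their neutrophil list rose (median 0.34, 1 of 5 members, Mpo; adjusted p = 0.876 with an estimated correlation). Keratinocytes had 2004 opened and 644 closed peaks, and 6461 and 5143 over the authors' own peak list, with calls of 1281 (without aged 1), 469 (aged 3), 607 (aged 4), 1008 (young 2), 383 (young 3) and 584 (young 4). The libraries labelled skin fibroblasts had 2065 and 490, 4885 and 1496 with the replicate block, whose numbers pair here, and calls of 1525 (without aged 1), 1242 (aged 3) and 838 (young 3).

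Kidney tubular cells closed histone gene peaks at H2bc22 (13:21787169-21787670, -1.87 ± 0.16) and H2ac15 (-1.98 ± 0.18), and opened peaks in the sulfotransferase gene Sult2a1 (7:13804132-13804633, 2.35 ± 0.26) and near Pura (18:36274761-36275262, 1.41 ± 0.16). Effector genes of T cells rose in 4 of 17 members and fell in 2, with Eomes at 0.51 ± 0.09 and Ccl3 at -0.60 ± 0.15 (adjusted p = 0.541 with an estimated correlation), and the endothelial marker list rose (median 0.38; adjusted p = 0.876 with an estimated correlation). Liver progenitors closed the same 13:21753710-21754211 peak at H2ac15, from 32.5 ± 1.94 to 4.59 ± 0.75 CPM (SD, n = 3 each; -2.83 ± 0.13), and the H1f5 peak (-2.97 ± 0.14). They opened peaks near Vav3 (3:109307278-109307779, 3.04 ± 0.24) and in Myzap (9:71542216-71542717, 2.73 ± 0.22). Their antigen presentation genes rose in 4 of 13 members (6 adjusted over the list alone), with Cd74 at 0.74 ± 0.08, and imprinted and growth genes fell in 4 of 15 (6), with Igf2bp3 at -0.58 ± 0.08 and Igf2 rising by 0.44 ± 0.10 (adjusted p = 0.537 with an estimated correlation for both). Their kidney endothelial marker list rose (median 0.28, 2 of 5 members, adjusted p = 0.876 with an estimated correlation). Kidney tubular cells had 12424 opened and 21200 closed peaks, 16047 and 18080 with library size scaling, and 21130 calls without aged library 2 and 19793 without young 2. Liver progenitors had 5530 and 4129, and 4981 calls without aged library 3, 6304 without young 1 and 5450 without young 3.

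Beta cells lost accessibility at some growth and cell cycle genes, though neither list passed with an estimated correlation. The RNA-binding protein gene Igf2bp2 fell by 2.03 ± 0.10 and Igf2bp3 by 0.45 ± 0.09, 2 of 5 members of 15 that fell (7 adjusted over the list alone), and the proliferation gene Mki67 by 0.91 ± 0.07 and the histone methyltransferase gene Ezh2 by 0.59 ± 0.08, 2 of 4 of 16 (5). Both lists had adjusted p = 0.282 with an estimated correlation. Peaks at Igf2bp2 (16:22162874-22163375, 22.2 ± 3.28, n = 5, to 3.39 ± 0.60 CPM, n = 3; -2.70 ± 0.17) and Ephb3 (16:21204413-21204914, -2.39 ± 0.15) closed, and a peak near Rps6ka5 (12:100742865-100743366, 4.93 ± 0.28) opened. The split of 12059 opened and 5607 closed was 16023 and 4064 with library size scaling, with 8560 calls without aged library 2.

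Neurons had 549 opened and 4283 closed peaks. Peaks in Ugt1a8 (1:88216507-88217008, 2.13 ± 0.25) and, inside the second chromosome 19 run, near Ide (19:37246846-37247347, 1.41 ± 0.20) opened, and a peak in Ddx59 (1:136418423-136418924, -1.63 ± 0.21) and the first Ppm1h peak closed. Antigen presentation genes rose in 0 of 13 members over all genes (2 adjusted over the list alone; list adjusted p = 0.01, and adjusted p = 0.537 with an estimated correlation). The share of counts in the own peak list was 52.7% ± 0.747 in aged and 56.5% ± 0.598 in young libraries (SD, n = 3 each). The split was 487 and 1391 over the authors' own peak list, with calls of 540 (without aged 1), 1260 (aged 2), 8529 (aged 3), 1726 (young 1) and 2181 (young 2).

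Adipocytes had 15622 opened and 57483 closed peaks. Peaks in Bcl2l10 (9:75347986-75348487, 40.7 ± 16.4 to 3.37 ± 0.52 CPM, n = 3 each; -3.62 ± 0.23) and near Gpam, which starts glycerolipid synthesis (19:55139289-55139790, -3.40 ± 0.22), closed, and peaks in Ide (19:37290852-37291353, 3.43 ± 0.47) and near Marchf5 (19:37235199-37235700, 3.01 ± 0.39), both beside the chromosome 19 runs, opened. Adipocyte markers fell in 6 of 7 members, but their list did not pass at the preset correlation. AP-1 genes fell in 10 of 14, rising in 2, with Junb at -0.80 ± 0.09. Immediate-early genes fell in 13 of 17, with Zfp36 at -1.29 ± 0.12, and clock genes in 13 of 16, with Nr1d2 at -1.04 ± 0.09. Each of these 4 lists had the same number adjusted over the list alone. T cell markers rose in 7 of 7, with Bcl11b at 1.13 ± 0.09, and effector genes in 15 of 17, with Ifng at 1.16 ± 0.10. These lists had adjusted p = 0.537 (AP-1, immediate-early, effector), 0.643 (clock) and 0.876 (T cell markers) with an estimated correlation. Beside them, the share of counts in the own peak list was 36.6% ± 1.65 in aged and 57.5% ± 2.23 in young libraries (SD, n = 3 each). Whether this lower signal moved the lists was not tested. The split was 20761 and 18320 over the authors' own peak list, 158180 and 32088 with library size scaling and 3366 and 55522 with DESeq2.

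Distal peaks lay above peaks within 1000 bases of a gene end in 13 of 23 cell types (exact two-sided sign test p = 0.678), from -0.64 in haematopoietic stem cells to 0.72 in adipocytes. Peaks most specific to a cell type lay above other peaks of like accessibility in 11 of 23 types (exact p = 1), lowest in naive CD4 (-0.57) and naive CD8 T cells (-0.35), while 54.3% of those of memory CD8 T cells opened. The share of counts near gene ends was higher in aged libraries in 12 of 23 types (exact p = 1). Changed peaks recurred, with 5802 peaks opened in 5 or more cell types against 1267.14 after shuffling calls and 5121 closed against 785.66. With the 5 T cell types counted as 1, a choice made after seeing the data, the numbers were 490 against 103.03 and 352 against 186.34. In the median cell type 43.9% of opened, 68.6% of closed and 34.4% of uncalled peaks overlapped the type's own young peak list. A difference between opened and closed peaks there is built into the calls, since closed peaks are those higher in young libraries.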

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

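All tests named in this part to weigh explanations were chosen after the results were seen.

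The age effect on 6 gene lists went in opposite directions in 2 cell types each. The pairs were chosen because the lists were called in opposite directions in them, so the difference was not tested apart from that choice. In 3 of the pairs the falling type is adipocytes, whose aged libraries had a lower share of counts in the own peak list (36.6% against 57.5%). The differences in log2 units were 0.54 for AP-1 genes (B cells 0.20, adipocytes -0.34), 0.59 for immediate-early genes (B cells 0.16, adipocytes -0.42), 0.72 for extracellular matrix genes (thymic epithelium 0.33, B cells -0.39), 0.42 for cell cycle genes (naive CD8 T cells 0.17, beta cells -0.25), 0.70 for clock genes (thymic epithelium 0.20, adipocytes -0.50) and 1.49 for T cell effector genes (naive CD8 T cells 1.27, lymph endothelium -0.22). Of 81 groups and measures, 3 held a library far from the others, and 4.05 would by chance. Muscle fibroblast young library 1 had 78.4% of counts in its own peak list, and the others 84.9% to 85.8%. B cell aged library 4 had a log2 ratio of counts in the chromosome 19 runs to their flanks of -2.33, and the others -1.57 to -1.56. Beta cell young library 3 had -1.69, and the others -1.76 to -1.75.

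Peaks in 3 runs on chromosome 19 were higher in aged libraries of 23 of 23 types, and 3 explanations were tested. If the copy number of the region differs between aged and young animals, peaks outside the peak lists should rise as much as listed ones, and they rose by 0.87 log2 units, or 1.82-fold, over their flanks, which leaves a copy number difference open. Opening of regulatory elements should raise listed peaks more, and they rose by 0.057 less (-0.057, SD 0.21 over 23 cell types). Unlisted peaks rose over their flanks in 23 of 23 types. These values argue against opening of elements as the source of the shift in these runs. The 2 aged libraries with little or no shift (0.19 and 0.02) could have come from young animals, but over called peaks outside both loci they lay at 0.668 or more of the way from the young to the aged mean. B cell aged library 4 lay at 0.668, the other aged B cell libraries at 0.696 to 0.731 and the young ones at 0.276 to 0.385, each held out in turn. Virtual memory CD8 aged library 4 lay at 0.803, the other aged ones at 0.814 to 0.878 and the young ones at 0.038 to 0.165. The source of the 2 exceptions and of the Ppm1h peak was not tested. A genotype difference between the cohorts of mice remains possible (0.87), so differences at these loci, and at others that differ between the cohorts, may reflect cohort in place of age.

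The libraries labelled skin fibroblasts held keratinocyte accessibility, and 3 explanations were tested. Keratinocytes sorted or labelled as fibroblasts predict low fibroblast markers, and the fibroblast list lay 3.17 log2 units lower than in other fibroblast types (-3.17). A minor share of keratinocytes predicts that most fibroblast peaks remain, and 10.2% of the peaks listed for fibroblasts and not for keratinocytes were listed here. Low signal predicts a low share of counts in the own peak list, and the lowest share was 83.8%.

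Adipocytes closed more peaks than they opened, and 2 explanations were tested. Lower signal over background in aged libraries predicts a fall within the own peak list and a rise outside it, and the medians were -0.88 and 0.21. Closing beyond the lower signal predicts an excess of closed peaks within the own list alone, where 46.9% of calls were closed. This test cannot tell, since the scaling holds the median of that list near 0 (0.015). From the shares of counts alone, listed peaks would shift by -0.65, and the median found was -0.88. Lower signal may account for part or all of the excess, and closing of elements with age cannot be told apart from it (46.9%).

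Calls by age were set against other splits of the same libraries on 10000 peaks. The age split called the most peaks of 35 splits, or 56 in beta cells, in 12 cell types, each with 1 split calling as many. Among T cells these were memory CD4 (3218 peaks, highest other 35), naive CD4 (2502, 43), memory CD8 (3210, 14), naive CD8 (2200, 84) and virtual memory CD8 (1697, 3). The others were B cells (760, 19), beta cells (802, 152), kidney endothelium (361, 39), kidney tubular cells (1546, 1307), lymph fibroblasts (420, 53), thymic epithelium (3248, 703) and thymic fibroblasts (549, 36). A share of 1 in 35 or 56 is the lowest this test can give, and it was not adjusted over the 23 types. It therefore does not exclude chance in any single type. The 10 splits were too few to tell in adipocytes (1637, highest other 0), fat progenitors (405, 1), liver progenitors (413, 2), lymph endothelium (194, 3) and neurons (147, 3). Where replicate numbers pair the libraries, only the splits that part every pair compare with the age split, and these were too few to tell, with 8 in brain endothelium (75, highest other 0) and in muscle fibroblasts (23, 0) and 4 in the libraries labelled skin fibroblasts (95, 0). Splits that keep at least 1 pair together called up to 43 and 17 peaks in the first 2. In haematopoietic stem cells (194 against 593), keratinocytes (98 against 1214) and satellite stem cells (44 against 1723), 2, 2 and 3 of 35 splits called as many, which points to a structure of the samples other than age. The keratinocyte split with 1214 set libraries 1 and 2 of both ages against libraries 3 and 4, so it kept same-numbered libraries together. Across cell types, 1 of 50 assignments of signs, the real one, called as many peaks (744, highest other 0) and as many genes (125, highest other 0). Signs were drawn for each of the 23 types on its own, so related types were not kept together. Since related types are not independent, this test does not exclude chance. With 8 classes of cell types as units, 12 peaks and 5 genes were called.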

How the results depend on the processing

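The tests in this part that were chosen after the results were seen are the older edgeR fit, the fits without 2 libraries, the T cell types counted as 1, and those without the chromosome 19 runs or 2 aged libraries. Counts of peaks depend on depth and on the spread of 3 to 5 pooled libraries per group, and 63 of 166 single libraries moved the count by over 1.5 times. Library size scaling moved the median of all peaks by over 0.1 in 6 cell types, from -0.45 in haematopoietic stem cells to 0.56 in adipocytes, and DESeq2 in 0 (-0.05 to 0.07), so the split into opened and closed rests on the scaling where both values are given in the report. The larger side also turned with the authors' lists in naive CD4 (15148 and 15782) and virtual memory CD8 T cells (9281 and 10829; 11059 and 16210 with library size scaling), with DESeq2 in memory CD8 T cells (31839 and 25484), and with no low-count filter in fat progenitors (51 and 116) and lymph fibroblasts (257 and 359). Across cell types 414 peaks opened and 281 closed with DESeq2, 586 and 308 over the authors' peak lists and 315 and 185 with the block, and the direction held. Fewer peaks are tested with the authors' lists and fewer libraries where some are left out; for the other values below the cause was not tested.

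Over the authors' peak list of the cell type the calls numbered 39081 in adipocytes, 6319 in brain endothelium, 34826 in memory CD4 T cells, 12207 in haematopoietic stem cells, 11604 in keratinocytes, 2013 in lymph endothelium, 1878 in neurons, 6247 in satellite stem cells and 59267 in thymic epithelium. With library size scaling they were 190268 in adipocytes, 4809 in brain endothelium, 6927 in keratinocytes, 2862 in neurons and 3299 in satellite stem cells. With no low-count filter they were 23876 in B cells, 9970 in beta cells, 1305 in brain endothelium, 26362 in memory CD4, 31023 in memory CD8 and 18149 in naive CD8 T cells, 167 in fat progenitors, 4988 in haematopoietic stem cells, 564 in keratinocytes, 1396 in kidney endothelium, 17059 in kidney tubular cells, 5355 in liver progenitors, 35 in lymph endothelium, 616 in lymph fibroblasts, 70 in muscle fibroblasts, 363 in satellite stem cells, 1691 in the libraries labelled skin fibroblasts and 6013 in thymic fibroblasts. With DESeq2 fat progenitors had 3509. The older edgeR fit gave 1613 in lymph endothelium, 3924 in lymph fibroblasts, 444 in muscle fibroblasts, 1908 in neurons, 1113 in satellite stem cells and 9340 in thymic fibroblasts. With the deposition set as a covariate there were 4685 in fat progenitors, 594 in lymph fibroblasts, 3123 in muscle fibroblasts and 178 in satellite stem cells, where this covariate nearly coincides with age. Without the aged lymph fibroblast libraries with conflicting labels there were 17377, and without aged library 2 and young library 1 there were 2118 in muscle fibroblasts and 6157 in satellite stem cells.

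With the replicate block, where numbers pair, calls numbered 4893 in muscle fibroblasts and 6381 in the libraries labelled skin fibroblasts, and in brain endothelium 987 opened and 972 closed, a count within 1.5 times of that without it. Same-number correlations ran from -0.376 to 0.527 over all types. In types short of the limit of 0.1 for pairing, the block gave 41096 in adipocytes, 11166 in beta cells, 9249 in keratinocytes and 14327 in kidney endothelium. It gave 18983 in liver progenitors, 11527 in lymph endothelium, 585 in satellite stem cells and 25071 in thymic fibroblasts. In haematopoietic stem cells edgeR with the block called 0 peaks, with 68312 at an unadjusted p under 0.05, where edgeR without it called 5170 opened and 2440 closed and DESeq2 7420 and 425. Every library was closest to its own number only in the libraries labelled skin fibroblasts (6 of 6).

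With each replicate left out in turn the lowest and highest counts were 7697 and 19000 in B cells, 8560 and 19682 in beta cells, 755 and 2444 in brain endothelium, 21966 and 51306 in naive CD8 and 17429 and 29582 in virtual memory CD8 T cells, 2062 and 7642 in fat progenitors, 3 and 153357 in haematopoietic stem cells, 383 and 2106 in keratinocytes, 3222 and 7588 in kidney endothelium, 19793 and 35796 in kidney tubular cells, 4981 and 12107 in liver progenitors, 139 and 5169 in lymph endothelium, 2446 and 11126 in lymph fibroblasts, 85 and 1924 in muscle fibroblasts, 540 and 8529 in neurons, 285 and 4211 in satellite stem cells, 838 and 2759 in the libraries labelled skin fibroblasts and 5813 and 17000 in thymic fibroblasts. In the other 5 cell types no library moved the count by over 1.5 times.

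Across cell types the peaks called numbered 12 with 8 classes as units, 286 when tested in at least 5 types, 254 with library size scaling, 138 with no low-count filter and 68687 with edgeR over all libraries, which takes libraries and not cell types as units. Without a cell type they numbered 2173 (adipocytes), 250 (memory CD4), 336 (naive CD4), 245 (memory CD8), 237 (naive CD8), 242 (virtual memory CD8), 457 (lymph fibroblasts) and 372 (thymic fibroblasts). Genes numbered 199 without adipocytes, 72 without brain endothelium, 52 without memory CD4, 56 without memory CD8, 66 without naive CD8, 58 without virtual memory CD8, 75 without lymph fibroblasts, 81 without satellite stem cells and 68 without thymic fibroblasts, 5 with 8 classes and 82 over gene-end peaks alone. With an estimated correlation 2 of 13 lists were called across cell types and 0 within them.

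Distal minus gene-end peaks turned to -0.024 over the authors' lists (exact sign test p = 0.678) and to -0.0086 within 2500 bases (p = 1), neither past the test. Specific minus other peaks was 8.0e-05 with DESeq2 (exact sign test p = 1), 0.052 ranked by aged libraries (p = 0.21), 0.0011 for the top 10% (p = 1) and -0.19 ranked by young libraries (p = 0.0026), a ranking that itself favours a fall with age. A peak that opened is lower in young libraries by definition, so this next comparison is not free of the calls. Opened minus uncalled peaks in the own young list was 6.35 points (14 of 23 types, exact sign test p = 0.405), 7.79 with at least 50% of the peak overlapping (p = 0.0931) and 11.7 with the block (p = 0.286), none past the test. It was -26.5 points over the authors' lists (exact sign test p = 2.4e-07), 11.9 with DESeq2 (p = 4.9e-04), 12.2 with library size scaling (p = 0.0106) and 15.6 with no low-count filter (p = 0.0347). Opened peaks numbered 26558 in 3 or more and 262 in 8 or more types, 490 with T cell types counted as 1 and 3583 with no low-count filter, and closed ones 22165, 164, 352 and 781, and 7809 with library size scaling. Batf3 was 0.013 over gene-end peaks alone (limma adjusted p = 0.974) and Npas2 in adipocytes -0.079 over the authors' list (edgeR adjusted p = 0.586).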

Other observations

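The regions and the gene in this part were chosen after their values were seen.

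Lncpint, a long noncoding RNA gene induced by p53 (6:31093563-31218474), holds 141 peaks. Their log2 sum was higher in aged libraries in 22 of 23 cell types, by 0.26 on average (SD 0.22 over 23 cell types) and by up to 0.89 in memory CD8 T cells. Peaks in it opened in 18 cell types and closed in 6, with 22 closed and 0 opened in adipocytes, and 16 of the 140 tested across cell types passed the threshold.

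Windows of 10 neighbouring peaks were searched for shifts of the same sign in at least 22 cell types, with a mean shift of at least 0.3 in size. Of 46458 windows, 17 passed, 8 of them on chromosome 19. Outside that chromosome the mean shift was 1.05 at 1:85109246-85247654, beside Sp110 and among gene models with many related copies, 0.59 at 13:31561523-31577217 and 0.41 at 17:35393842-35422733, around H2-Q5. Windows with at least 20 cell types of the same sign held Nlrc5 (8:94447480-94484696, 0.47), H2-T3 (17:36154409-36187967, 0.51) and, lower in aged libraries, Dnajc3 and Uggt2 (14:118958109-118987124, -0.58). These fell short of the limit of 22 cell types and are examples from a longer list. The exact sign test gave an adjusted p of 0.0353 for the Nlrc5 window. It gave 0.0788 for the H2-T3 window and for that of Dnajc3 and Uggt2, not past the threshold.

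Among single peaks, the Sox11 peak closed in 8 of 18 cell types and opened in 0, and the Gnas peak closed in 8 of 20 and opened in 0. The Peg3 peak closed in 8 of 22 types and opened in 3, and the Igf2bp2 peak closed in 8 of 23 and opened in 1. Histone gene peaks closed in 9 types each at H1f5, H2bc22 and H3c11, and opened in 2, 4 and 2. Peaks beside Prkcz, Cd74 and H2-Q6 opened in 11, 10 and 10 types and closed in 0, 0 and 1.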
